A study of Mus musculus with 4 samples.

How the data were processed

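Gene expression was measured in ureters dissected from mouse embryos of the NMRI strain at E14.5 (embryonic day). The mutants carried a cre allele at Tbx18, a transcription factor gene of the ureteric mesenchyme, together with floxed alleles of Fgfr1 and Fgfr2, which encode fibroblast growth factor (FGF) receptors; they are called cDKO (conditional double knockout) here. Controls carried at least 1 floxed allele of each receptor gene and no cre allele in the labels. Each of the 4 arrays held cDKO RNA in one channel and control RNA in the other, and both channels of an array carried the same sex label. The cDKO RNA was in the red channel (Cy5) on replicates 1 and 3 and in the green channel (Cy3) on replicates 2 and 4. The labels name no animals or pools behind a replicate, so p-values measure the spread between these 4 pairs of extracts.

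Per the labels' protocols, the authors extracted total RNA with peqGOLD RNAPure, amplified and labelled 150 ng of it with a low-input kit for 2 colours, and hybridised it to Agilent arrays. Per the file headers, the scans were quantified with Agilent Feature Extraction 10.7.3.1, and probe coordinates are those of mouse build mm9. The deposited scanner files give mean spot intensity and median local background intensity for each channel, not yet normalized. Per the file headers, they also give processed intensity values, background subtracted and dye normalized by the scanner software, and log10 ratios of red over green. The authors' deposited value table gives another quantity per probe and array, a signed fold in which no value lies between -1 and 1; its sign was settled by setting each column against the scanner values. The correlation across probes with the log ratio of red over green was 0.959 and 0.953 on replicates 1 and 3, and -0.963 and -0.96 on replicates 2 and 4, so a positive fold means a higher cDKO signal. Each column of that table has a median of 1, and between 10624 and 11152 probes per array are listed at exactly 1. How the table was centred and how those probes were chosen is not given in the sources used here. No column lacked a sample.

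Mean spot intensity was corrected with normexp (offset 50) and log2 ratios were normalized within each array by loess (span 0.3), with control spots and spots marked as outliers given no weight. The unmarked spots among the 4 of each probe were averaged. A probe was kept if at least 3 of its 4 spots were well above background on all 4 arrays in the cDKO channel or on all 4 in the control channel, which left 25591 of 39429 probes (64.9%). Where a gene had several kept probes, the one with the highest mean intensity was used. Of the 42 called genes with several probes, 41 had every probe on the same side of 0. Probes were named through their accession in a table of RefSeq genes (28328 probes), by a file name that is a current symbol (3400) or by a synonym (243); 7458 kept the name in the file. Levels per channel, on the log2 scale, were taken after quantile scaling of mean intensities between arrays.

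Ratios were fitted in R 4.3.3 with limma 3.58.1 (lmFit and eBayes) with a term for the dye and a term for genotype. Tests were two-sided, with Benjamini-Hochberg adjustment over the 19365 genes, and a gene was called at an adjusted p under 0.05. The fit left 2 residual degrees of freedom beside the 4.53 of the prior. Errors are standard errors (SE) of the fit over n = 4 arrays unless stated otherwise. The 25 gene lists of pathways and cell types were tested with limma's camera at a preset correlation of 0.01. The alternatives were camera with an estimated correlation and fry, both directional and mixed. Differences of the cDKO effect between the sex labels, and gene-specific dye effects, were tested in the same framework. Slide was taken from the headers: replicates 1 and 2 lay on slide 1 with scan 1, and replicates 3 and 4 on slide 2 with scan 2, on different scanners. The same fit on simulated arrays with 200 changed genes among 19365, for the comparison of cDKO with control, recovered 62.7% of genes changed 1.5-fold, 94% of those changed 2-fold and 100% of those changed 3-fold, and 6.56% of its calls were unchanged genes. Its gene variances were drawn from the fitted prior, and it held no slide differences. A first version of the simulation, with each gene's moderated variance, was judged too even and replaced after its result was seen; with those variances the recovery was 94%, 100% and 100%, and 7.98% of the calls were unchanged genes.

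The lists, the tests and the rule for named genes were fixed before the data were examined. The rule names Fgfr1, Fgfr2 and Tbx18, the 10 largest rises and the 10 largest falls among called genes with the same direction on all 4 arrays and a symbol that is not a clone or predicted-gene name, and for each list up to 4 called members with the smallest p, or the 2 measured members with the smallest p where none was called. All members are named where a list has 5 or fewer. Some genes that this rule names are not reported here. Alternatives covered the dye, sex and slide terms, background correction, normalization, the scanner software's processed signals, the authors' value table, the filter on dim probes, the choice of probe, outlier spots, array weights, the variance trend, a fit of the separate channels (statmod 1.5.0), a rule of size without a p-value, and leaving out each replicate. The number of arrays limits the precision. No genome sequence or annotation of build mm9 was used here, so the exon or untranslated region in which a probe lies is not stated. Figures were drawn with matplotlib 3.10.9.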

Results

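The data comprised 4 two-colour arrays, each comparing ureters of cDKO embryos, whose labels give floxed alleles of Fgfr1 and Fgfr2 and a cre allele at Tbx18, with control ureters at E14.5. Each array held 157716 spots for 39429 probes. The median spot signal lay between 138.7 and 383.4 in the cDKO channels and between 169 and 417.3 in the control channels. The share of spots well above background was 66.1% to 71.8% in the cDKO channels and 64.9% to 72.6% in the control channels. No spot was saturated. The comparison asks which transcripts of the ureter differ between these genotypes.

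The targeted genes were examined first. Fgfr1 was covered by kept probes at several positions on chromosome 8. The brightest, at 26685072 to 26685131 (mm9), gave a log2 ratio of -0.40 ± 0.10 (SE, n = 4) with an adjusted p of 0.117, which did not pass the test, and was negative on all 4 arrays. The probe at 26684061 to 26684120 gave -0.54 ± 0.07 (adjusted p over probes = 0.0406), and the probe at 26685820 to 26685879 gave -0.03 ± 0.08 (adjusted p over probes = 0.872). Fgfr2 rose (log2 ratio 0.59 ± 0.07, adjusted p = 0.0356) at its brightest probe, chromosome 7 from 137307473 to 137307532, and the overlapping probe from 137307455 gave 0.56 ± 0.08 (adjusted p over probes = 0.0537). Tbx18, the locus that carries cre, gave 0.26 ± 0.08 (adjusted p = 0.164) at chromosome 9 from 87599514 to 87599573. The position of the deleted part of each gene is not given in the sources used here, and a probe outside it checks nothing, so these values neither check nor contradict the genotype labels. With the slide as a term beside the dye, the adjusted p was 0.0114 for Fgfr1, 0.00235 for Fgfr2 and 0.044 for Tbx18. The log2 ratios on slides 1 and 2 were -0.22 and -0.57, 0.59 and 0.58, and 0.36 and 0.16. That fit left 1 residual degree of freedom and takes the difference between slides out of the error. Its p-values therefore do not measure the spread between the 4 pairs. The call of Fgfr2 was lost with a sex term (adjusted p = 0.104), within slide 1 (0.06) and within slide 2 (0.374), with median centring (0.081) and without the filter (0.0833). It was also lost without replicates 1 (0.146) and 2 (0.065), and on the female-labelled (0.174) and male-labelled (0.735) arrays alone. Only the settings on the arrays of 1 sex label were chosen after seeing the data. Those settings and the fits within 1 slide had no dye term.

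**Figure D1:**
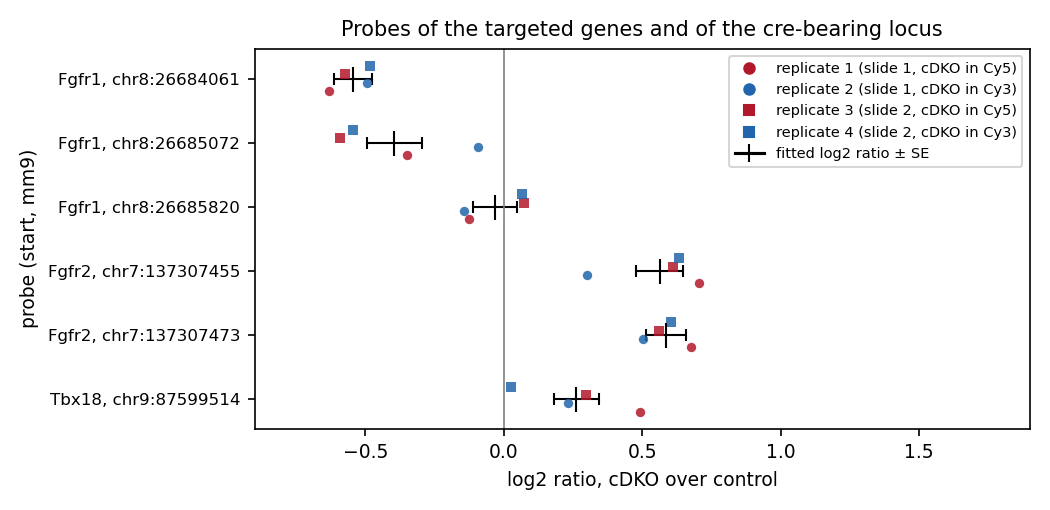
Log2 ratio of cDKO over control (x axis) for each kept probe of Fgfr1, Fgfr2 and Tbx18 (y axis, labelled with its mm9 start). Points are the 4 arrays, circles on slide 1 and squares on slide 2, coloured by the dye of cDKO, and black bars are fitted ratios ± SE. Both Fgfr2 probes lie above 0 on all 4 arrays, from 0.299 upwards.

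Between cDKO and control ureters, 165 of 19365 genes changed, of which 107 rose and 58 fell. The largest rise was that of Aldh1a3, an enzyme that makes retinoic acid, which was 4.15-fold higher (log2 ratio 2.05 ± 0.12, adjusted p = 0.012; probe on chromosome 7 from 73535785 to 73535844). Among called genes with a symbol that is not a clone or predicted-gene name it was followed by Sp5, a transcription factor gene activated by WNT signalling, which rose 2.72-fold (1.45 ± 0.11, adjusted p = 0.0213). Cntn1, a neural cell adhesion molecule (2.53-fold), Gria1, a glutamate receptor subunit (2.35-fold), and Tfcp2l1, a transcription factor of kidney collecting ducts (2.12-fold), rose too. The other named rises were ccdc198 (2.06-fold), the potassium channel gene Kcnma1 (2.03-fold), the integrin gene Itga4 (1.97-fold), Spink8 (1.97-fold) and the ephrin receptor gene Epha8 (1.95-fold). The largest fall was that of Upk1b, which encodes a uroplakin of the urothelial surface, at a log2 ratio of -1.43 ± 0.20 (adjusted p = 0.0401; probe on chromosome 16 from 38773859 to 38773918). Anxa8 (-1.19), Zdhhc22 (-1.13), Perp, which encodes a protein of desmosomes in stratified epithelia (-1.05), and Sprr1a, a precursor of the cornified envelope (-0.97), fell next. The remaining named falls were Batf (-0.89), Aldh3b2 (-0.88), Fmo1 (-0.87), the small proteoglycan gene Aspn (-0.86) and Ptn, which encodes a heparin-binding growth factor (-0.86). The adjusted p of these 20 genes lay between 0.012 and 0.0422, and the sign was the same on all 4 arrays for each, as the naming rule required. Over all genes tested, the Pearson correlation of the log2 ratios between arrays ranged from 0.006 (replicates 2 and 3) to 0.507 (replicates 1 and 2). All 165 called genes kept 1 direction over the 4 arrays, 119 changed at least 1.5-fold (85 rose and 34 fell), and 13 at least 2-fold (9 rose and 4 fell). The median size of a called change was 0.69 on the log2 scale.

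The test was limma's, and 3789 genes had an unadjusted p under 0.05. The count depended on the terms of the fit. With the slide as a term beside the dye it was 2418 (1552 rose and 866 fell, all 165 among them). That fit left 1 residual degree of freedom and took the difference of the cDKO effect between slides out of the error. Its p-values thus do not measure the spread between the 4 pairs. With a sex term the count was 2. Within slide 1 it was 551 and within slide 2 it was 0 (1346 at an unadjusted p under 0.05), both of these without a dye term. Without a filter on dim probes 1 gene was called, and without replicates 1, 2, 3 and 4 in turn the counts were 34, 56, 266 and 403.

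**Figure D2:**
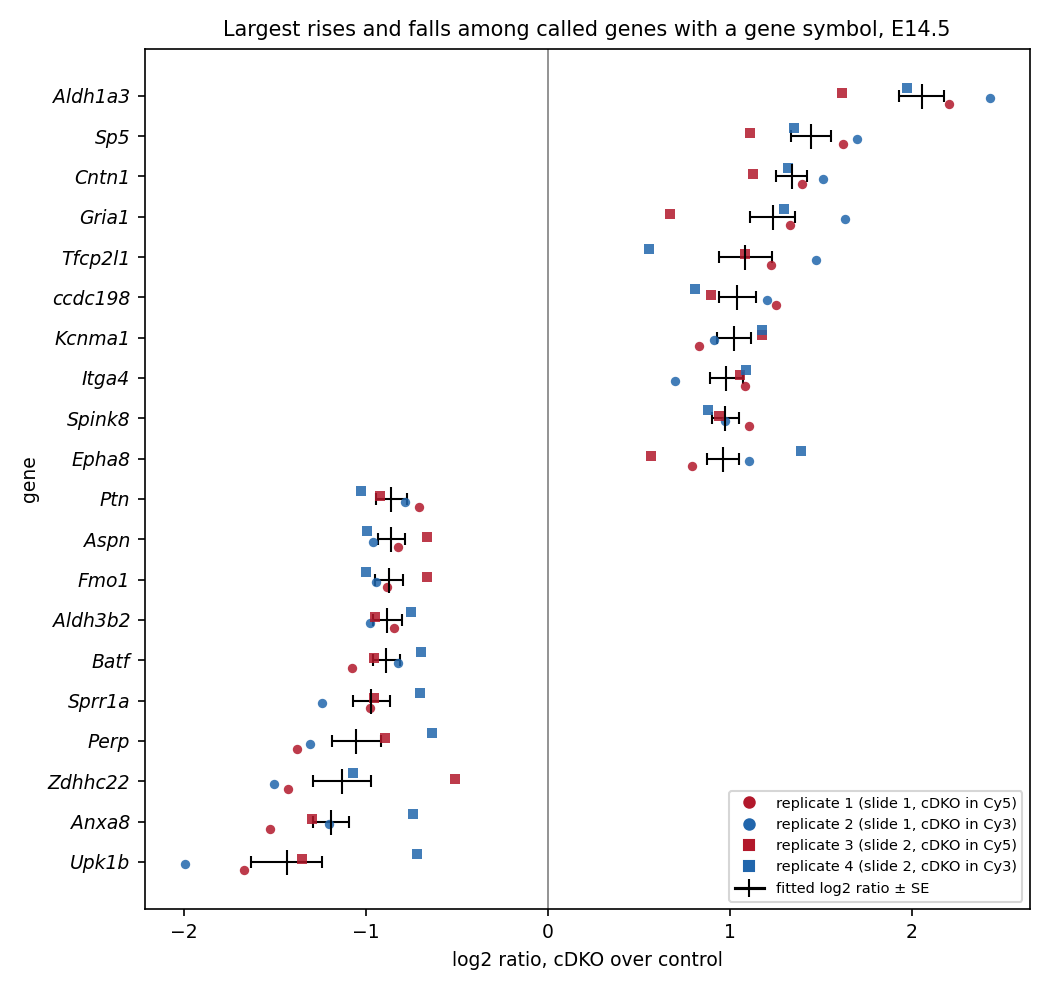
Log2 ratio of cDKO over control (x axis) for the 10 largest rises and 10 largest falls among called genes whose symbol is not a clone or predicted-gene name (y axis). Points are the 4 arrays, circles on slide 1 and squares on slide 2, coloured by the dye of cDKO, and black bars are fitted ratios ± SE. Aldh1a3 lies between 1.61 and 2.43 and Upk1b between -2.00 and -0.72, and no gene has an array on the other side of 0, as the naming rule required.

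Of the 25 lists, 10 were called by camera at the preset correlation, 5 up and 5 down. With an estimated correlation none was, the adjusted p of these 10 lying between 0.543 and 0.634. That variant has only the 2 residual degrees of freedom of the fit, so it has little power here. The loss of a call with it does not show that correlation among members made the call. The endothelial list lost its call too, although its estimated correlation was -0.041, below the preset 0.01. Genes of the Sonic hedgehog (SHH) pathway rose as a list (median log2 ratio 0.30, adjusted p = 6.33e-06; adjusted p = 0.543 with an estimated correlation), and all 13 measured members lay above 0. Of them 3 passed over all genes, namely Foxl1, a forkhead gene activated by hedgehog signalling (0.95 ± 0.10), the receptor gene Ptch1 (0.55 ± 0.08) and the decoy receptor gene Hhip (0.62 ± 0.09), both of which are induced by the pathway, and 8 rose when adjusted over the list alone. The list's median was 0.39 on slide 1 and 0.17 on slide 2. Genes of the WNT pathway also rose as a list (median 0.18, adjusted p = 0.000597; adjusted p = 0.543 with an estimated correlation). Sp5 and the negative feedback gene Axin2 (0.74 ± 0.09) were its 2 called members among 18, and adjusted over the list alone 5 rose and 1 fell. Its median was 0.27 on slide 1 and 0.13 on slide 2. The retinoic acid list was called up (median 0.18, adjusted p = 0.00578; adjusted p = 0.634 with an estimated correlation) with members on both sides. Aldh1a3 and Cyp26a1, which breaks retinoic acid down (0.74 ± 0.09), rose, and Crabp1, which encodes a retinoic acid binding protein (-0.65 ± 0.08), fell, out of 13 measured. Adjusted over the list alone 6 rose and 1 fell, and the median was 0.23 on slide 1 and 0.13 on slide 2.

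The list most directly tied to the targeted receptors was not called. Of 13 measured FGF response genes none was called (median 0.12, adjusted p = 0.226), and 1 rose when adjusted over the list alone. Its median was 0.28 on slide 1 and -0.02 on slide 2, and the list was called up within slide 1 (adjusted p = 0.0273), without replicate 4 (0.0391) and on the male-labelled arrays alone (0.0399). The 2 with the smallest p were Spry1 (0.41 ± 0.08, adjusted p = 0.0669) and Etv5 (0.35 ± 0.10, adjusted p = 0.146). Among the 9 measured FGF ligands and other receptors the ligand gene Fgf9 rose 1.79-fold (0.84 ± 0.07, adjusted p = 0.0213), and adjusted over the list alone 2 rose and 1 fell. That list was not called (adjusted p = 0.503), and its median was -0.04 while its mean was 0.12. Bone morphogenetic protein (BMP) pathway genes had no called member among 17 (median 0.10, adjusted p = 0.102), with 6 higher and 2 lower adjusted over the list alone. Chrdl1, which encodes a BMP antagonist, stood at 0.42 ± 0.07 (adjusted p = 0.0611) and the ligand gene Bmp5 at -0.46 ± 0.08 (adjusted p = 0.0642). The NOTCH list had none among 13 (median -0.07, mean 0.004, adjusted p = 0.929), camera and fry gave it opposite signs, and 3 rose adjusted over the list alone. Its members with the smallest p were Notch2 (0.45 ± 0.12, adjusted p = 0.12) and Jag1 (0.32 ± 0.08, adjusted p = 0.122).

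**Figure D3:**
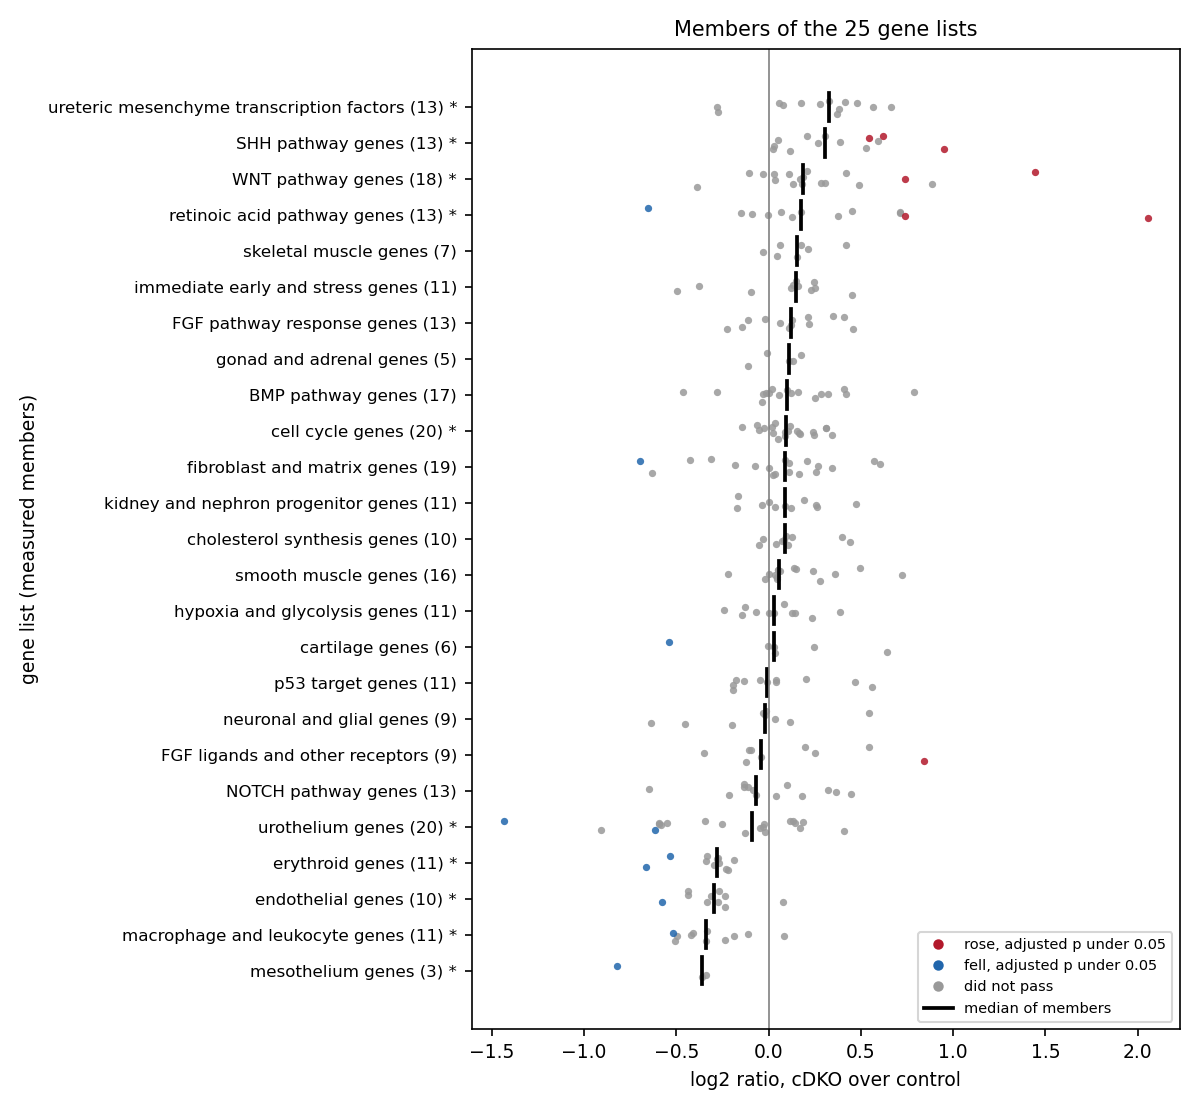
Log2 ratio of cDKO over control (x axis) for each measured member of the 25 lists (y axis, number measured in parentheses), sorted by median. Points are genes, red and blue for called rises and falls and grey for the others, black ticks are medians, and an asterisk marks lists called by camera at the preset correlation. The list of mesothelium genes has the lowest median, -0.36, and that of mesenchyme transcription factors the highest, 0.33.

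Among the tissues of the ureter, transcription factors of the ureteric mesenchyme were called up as a list (median 0.33, adjusted p = 0.00265; adjusted p = 0.634 with an estimated correlation). None of the 13 passed over all genes, while 8 rose and 2 fell adjusted over the list alone. Tshz3, required for smooth muscle formation in the ureter, stood at 0.38 ± 0.08 (adjusted p = 0.0953). The medians were 0.47 on slide 1 and 0.15 on slide 2. Smooth muscle genes had no called member among 16 (median 0.06, adjusted p = 0.0671), and 1 rose adjusted over the list alone. The medians were 0.21 on slide 1 and 0.03 on slide 2. Synpo2 stood at 0.72 ± 0.12 (adjusted p = 0.0558) and Myl9 at 0.28 ± 0.07 (adjusted p = 0.125). Fibroblast and matrix genes were not called as a list (median 0.09, adjusted p = 0.866, with fry of the opposite sign); of 19, the growth factor gene Igf1 fell (-0.69 ± 0.09), and adjusted over the list alone 3 rose and 3 fell. Urothelium genes were called down as a list (median -0.09, mean -0.25, adjusted p = 0.00426; adjusted p = 0.543 with an estimated correlation). Upk1b and the keratin gene Krt20 (-0.62 ± 0.08), both of superficial urothelial cells, fell out of 20, and adjusted over the list alone 8 fell and 1 rose. The medians were -0.26 on slide 1 and -0.07 on slide 2.

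Of the 9 lists of other cell types that the dissected samples could hold, 4 were called, each of them down. Erythroid genes were lower as a list (median -0.28, adjusted p = 3.38e-07; adjusted p = 0.543 with an estimated correlation), with all 11 measured members below 0. The embryonic globin genes Hba-x (-0.66 ± 0.09) and Hbb-bh1 (-0.54 ± 0.07) fell, and 9 fell adjusted over the list alone. The macrophage and leukocyte list (median -0.34, adjusted p = 2.03e-06; adjusted p = 0.543 with an estimated correlation) contained 1 called gene, Fcer1g (-0.52 ± 0.08), and 10 of its 11 members lay below 0, 8 of them passing when adjusted over the list alone. In the endothelial list (median -0.29, adjusted p = 1.1e-05; adjusted p = 0.543 with an estimated correlation) Emcn fell (-0.58 ± 0.07) out of 10, and 6 fell adjusted over the list alone. Mesothelium genes were called down too (median -0.36, adjusted p = 0.000235; adjusted p = 0.543 with an estimated correlation), with Msln (-0.82 ± 0.09) the only called gene of 3. Gpm6a stood at -0.36 ± 0.07 and Upk3b at -0.34 ± 0.08, and all 3 passed adjusted over the list alone. The control levels of Gpm6a and Upk3b were 7.655 and 7.245 (log2), close to the floor, and Upk3b stood at 0.05 on replicate 3. The fall of this list therefore rests mainly on Msln. On slides 1 and 2 the medians were -0.33 and -0.26 for erythroid, -0.44 and -0.31 for macrophage, -0.19 and -0.41 for endothelial and -0.39 and -0.35 for mesothelium genes. Kidney and nephron progenitor genes had no called member among 11 (median 0.09, adjusted p = 0.476, none adjusted over the list alone), with Pax8 at 0.47 ± 0.13 and Cdh6 at 0.19 ± 0.09. None of 9 neuronal and glial genes passed (median -0.02, adjusted p = 0.33), 1 was lower adjusted over the list alone, and S100b stood at -0.46 ± 0.10 and Th at -0.64 ± 0.21. That list's median was -0.34 on slide 1, where it was called down (adjusted p = 0.00744), and 0.16 on slide 2 (adjusted p = 0.693), and it was called down without replicate 3 (0.0011) and on the female-labelled arrays alone (0.00773). No gonad and adrenal gene passed among 5 (median 0.11, adjusted p = 0.601, none adjusted over the list alone), namely Amhr2 (0.13 ± 0.08), Cyp11a1 (0.11 ± 0.07), Dhh (0.18 ± 0.27), Cyp17a1 (-0.11 ± 0.26) and Nr5a1 (-0.007 ± 0.078). No skeletal muscle gene passed among 7 (median 0.15, adjusted p = 0.31, none adjusted over the list alone), with Acta1 at 0.18 ± 0.09 and Myh3 at 0.42 ± 0.29. The cartilage list was not called (median 0.03, adjusted p = 0.722); of 6, Hapln1, a matrix link protein gene, fell (-0.54 ± 0.08), and adjusted over the list alone 1 rose and 1 fell.

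Among general processes, cell cycle genes were called up as a list (median 0.10, adjusted p = 0.0332; adjusted p = 0.634 with an estimated correlation), with no called member among 20 and 1 higher adjusted over the list alone. Aurkb stood at 0.34 ± 0.07 (adjusted p = 0.0853) and Mcm3 at 0.31 ± 0.08, and the medians were 0.17 on slide 1 and 0.07 on slide 2. The call of this list was lost in 10 of 23 other camera settings, among them a slide term (adjusted p = 0.0539), within slide 1 (0.12) and slide 2 (0.113), median centring (0.234), and without replicates 2 (0.216) and 3 (0.174). The p53 target list was not called (11 measured, none called, 1 higher adjusted over the list alone; median -0.006, mean 0.05, adjusted p = 0.958), with Pmaip1 at 0.56 ± 0.11 and Cdkn1a at 0.47 ± 0.13. Nor were immediate early and stress genes (11 measured, none called, none adjusted over the list alone; median 0.15, adjusted p = 0.31), with Jun at 0.45 ± 0.11 and Egr2 at 0.25 ± 0.14. Their direction turned between slides, with a median of -0.18 and a called fall within slide 1 (adjusted p = 0.00479) and a median of 0.55 and a called rise within slide 2 (adjusted p = 3.63e-07). Both calls are camera's at the preset correlation of 0.01, while the estimated correlation of this list was 0.57. The median was 1.025 on replicate 3 and 0.249 on replicate 4, so the slide 2 rise came mostly from replicate 3. This list was chosen for RNA quality and handling rather than as a general process. Hypoxia and glycolysis genes (11 measured, none called, 1 higher adjusted over the list alone; median 0.03, adjusted p = 0.791) included Pfkfb3 at 0.39 ± 0.08 and Ldha at 0.23 ± 0.07. Cholesterol synthesis genes (10 measured, none called, none adjusted over the list alone; median 0.09, adjusted p = 0.161) included Sqle at 0.40 ± 0.13.

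The arrays also allowed a comparison between sex labels, since 2 carried female and 2 male labels. No gene's cDKO effect was called as different between the sex labels in limma (0 called, 207 at an unadjusted p under 0.05, lowest adjusted p = 0.486), in a fit that left 1 residual degree of freedom, and none had a dye effect (0 called, 1704 at an unadjusted p under 0.05, lowest adjusted p = 0.176). On these arrays the sex term has the same sign pattern as a difference in dye bias between slides, so the fit cannot separate them. Its 1 residual degree of freedom is the difference of the cDKO effect between slides, which was called for 173 genes in limma. Transcripts of the other sex were present in several channels, so the labels may not stand for samples of a single sex, which limits what this comparison can show. The Y-linked genes Ddx3y and Eif2s3y stood at 23% and 22% of the mean of male-labelled channels in the control channel of replicate 1, which is labelled female, and at 11.5% and 9.6% in the cDKO channel of replicate 4, also labelled female. In the cDKO channel of replicate 1 they stood at 5.33% and 4.2%, and in the control channel of replicate 4, where they were not well above background, at 1.88% and 1.4%. Xist, transcribed from the inactive X chromosome, stood at 23.2% of the mean of female-labelled channels in the control channel of replicate 2 and at 6.56% in that of replicate 3, both labelled male, and was not well above background in the cDKO channels of those replicates. Uty, also Y-linked, was well above background in the control channel of replicate 1 and in none of the other female-labelled channels, and Kdm5d was above it in 3 of the 4 male-labelled channels and in no female-labelled channel.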

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

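Among the tests given here, those of a dye bias, of red blood cells alone, of the Fgfr2 probes and of other sign patterns were chosen after the result was seen. A single array lay far from the other 3 by Dixon's ratio for 6 of the 96 values examined (71 named genes and 25 lists), and chance alone gives about 1 in 20. Itga4 stood at 0.698 on replicate 2 against 1.06 to 1.09 on the others. Aurkb stood at 0.301 on replicate 4 against 0.353 to 0.363. The median of the FGF response genes was 0.287 on replicate 2 against 0.0122 to 0.0528, that of the smooth muscle genes 0.241 on replicate 2 against 0.0288 to 0.0614, and that of the skeletal muscle genes 0.381 on replicate 2 against 0.0082 to 0.0436. The median of the WNT pathway genes was 0.0143 on replicate 3 against 0.261 to 0.296. With 4 arrays there are 7 sign patterns, the real one included as 1 of them, which is too few for a share under 0.05. The real pattern gave 165 genes in limma and the highest of the others 0, with up to 1810 genes at an unadjusted p under 0.05. The fits of the other patterns left any real genotype effect in their error, which lowers their calls. The comparison of 165 with 0 therefore decides nothing.

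Erythroid, macrophage and endothelial lists were lower in cDKO, at medians of -0.28, -0.34 and -0.29. A dye bias as the whole of the pooled fall is argued against, since the pooled members had a median below 0 on all 4 arrays, the highest being -0.256. A trend with brightness is argued against likewise, since 0 of 10000 random lists of the same size and brightness reached the observed -0.305. Single lists differed by array. On replicates 1, 2, 3 and 4 the medians were -0.38, -0.36, -0.11 and -0.54 for erythroid genes. They were -0.59, -0.34, -0.22 and -0.48 for macrophage and -0.38, 0.005, -0.53 and -0.30 for endothelial genes. The endothelial list was thus not lower on replicate 2. The median of a single array can carry a dye bias. Each slide held both dye orientations, so a bias equal on both arrays of a slide cancels from the fitted ratios and their list medians. A lower share of such cells in the cDKO samples was tested on further marker genes that the fixed lists did not hold. Of these 38, 30 lay below 0, and their pooled median was -0.215 and negative on all 4 arrays, which is what that explanation needs of the pool. The parts differed on replicate 2, with medians of -0.026 for endothelial, -0.27 for macrophage and -0.16 for erythroid genes. Of the 15 endothelial genes 13 lay below 0, but Flt1 (0.005) and Flt4 (0.02) did not. These lists were written when the called genes were known, and Pf4, a called gene (-0.63), was taken out of the macrophage one after its value was seen; the macrophage part had a median of -0.35, the endothelial part -0.25. For red blood cells the evidence is divided: all 11 genes of the fixed list lay below 0, but the 13 further genes had a median of -0.0587 against -0.28. Their median control level was 7.85 (log2), close to the floor, and the brighter ones, Hemgn (0.12), Slc25a37 (0.007), Epor (-0.06), Tspo2 (-0.28) and Ermap (-0.09), lay on both sides of 0 and did not pass the test. The markers give transcript levels rather than cell numbers, so a lower share itself stays open. If there was one, whether cDKO ureters held fewer of these cells or the dissections carried less cannot be told apart from these samples.

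Fgfr2, a targeted gene, was higher in cDKO at both probes. A single faulty probe or a dye bias is argued against by ratios above 0 for both probes on all 4 arrays, the lowest being 0.299, although the probes overlap, so a related transcript that binds their shared part stays open. A larger share of epithelium, which has no history of Tbx18 expression and keeps Fgfr2, is argued against by a median of 0.0961 over 15 pan-epithelial genes (SD 0.183) against 0.59 for Fgfr2. Those 15 ranged from -0.11 (Rab25) to 0.51 (Cldn3), none of them called, with Spint1 at 0.40 and Cldn7 at 0.38 next to Cldn3; Cdh1, Epcam, Krt8 and Krt18, which the fixed urothelium list also held, stood at -0.02, -0.05, -0.02 and 0.13. A transcript of the recombined allele that still carries the probed part, or a response of the remaining cells, may account for it and was not tested.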

How the results depend on the processing

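Of the settings tried, those on the arrays of 1 sex label alone were chosen after seeing the data. These and the fits within 1 slide also had no dye term, so fewer arrays are not the only thing changed in them. Signal over background limits the dim probes, which the filter leaves out. The cause of each change below was not tested, except where a replicate left out or more genes tested is the setting itself. All called genes that a setting tested kept their sign in it, which follows on fewer arrays from their equal sign on all 4, and SHH, WNT, retinoic acid, mesenchyme transcription factor, urothelium, erythroid, macrophage and endothelial lists were called in each of the 23 camera settings at the preset correlation, mesothelium in 22 (adjusted p = 0.0508 without the filter) and cell cycle in 13. Lists not called were called in some of them: smooth muscle in 7, immediate early in 4, FGF response and neuronal in 3 each, skeletal muscle in 2 and BMP in 1. The count of 165 became 258 without a dye term, 2418 with a slide term beside it (1 residual degree of freedom) and 514 with the slide term in its place. With an offset of 16 it was 263, with median centring 255 (109 of them shared), with a variance trend 380 and in the separate-channel fit 1668. It became 551 within slide 1 (98 shared), 0 within slide 2 (1346 at an unadjusted p under 0.05), 2 with a sex term, 1 without the dim filter, where 29875 genes were tested, and 43 by size without a p-value. Without a dye term it was 2 on the female-labelled arrays and 0 on the male-labelled ones (959 at an unadjusted p under 0.05). Without 1 replicate it ranged from 34 to 403, namely 34, 56, 266 and 403 without replicates 1, 2, 3 and 4, sharing 27, 47, 106 and 148 genes with the 165. Of the 36 named genes called, 17, 24, 28 and 35 kept their call without these replicates, 1 with a sex term, 28 within slide 1, 30 with median centring, and 0 within slide 2 and without the filter; none turned. Fgfr2 had an adjusted p of 0.146 without replicate 1 and 0.065 without replicate 2. In 7 other settings, among them the scanner software's processed signals (214) and the authors' value table (214), it stayed within 1.5 times. The cDKO effect differed between slides for 173 genes. Of the lists, 0 were called with an estimated correlation, a test with 2 degrees of freedom. Directional fry called 0 and mixed fry 14, against between 9 and 14 elsewhere. Median centring gave 787 genes a dye effect, and 1 gene differed between the sexes with it and 1 with processed signals.

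The results that turned their direction had none of them passed the test. Adjusted p of the NOTCH list was then 0.9715 with the slide term in place of the dye term, 0.1997 within slide 1, 0.6678 on male-labelled arrays, 0.866 by directional fry, and without replicates 3 (0.6692) and 4 (0.5371). Over the fits without 1 replicate it ranged from 0.2899 to 0.6692. For fibroblast and matrix genes it was 0.3181 within slide 2, 0.5222 with median centring, 0.9277 with both channels above background, 0.735 on male-labelled arrays, 0.9407 by directional fry, and without replicates 1 (0.5143) and 2 (0.8622), in a range of 0.3271 to 0.8622. For p53 targets it was 0.98 without a dye term, 0.9886 with a sex term, 0.9486 with a slide term beside the dye, 0.9424 with it in place of the dye, 0.9622 within slide 1, 0.8848 within slide 2, 0.6087 with median centring, 0.948 with the mean of probes, 0.297 on male-labelled arrays, 0.8044 by directional fry, and without replicates 1 (0.5143) and 4 (0.6485), in a range of 0.5143 to 0.8322. Gonad and adrenal genes gave 0.9622 within slide 1, 0.8424 without the filter, 0.1707 on female-labelled arrays, and 0.8622 and 0.6296 without replicates 2 and 3, in a range of 0.07558 to 0.8622. Neuronal genes gave 0.6926 within slide 2, 0.871 on male-labelled arrays and 0.3001 without replicate 1, in a range of 0.001097 (a called fall, without replicate 3) to 0.7721. Skeletal muscle genes gave 0.9392 within slide 2, 0.9359 on female-labelled arrays and 0.8766 without replicate 2, in a range of 0.02615 (without replicate 4) to 0.8766, and kidney genes 0.9359 on female-labelled arrays. Immediate early genes turned to a called fall within slide 1 (0.004787), with 0.4834 on female-labelled arrays and 0.08068 without replicate 3, in a range of 8.997e-08 (a called rise, without replicate 1) to 0.6979, and hypoxia genes gave 0.9554 within slide 2. Log2 ratios that turned were those of Dhh (-0.2086 within slide 1, -0.3764 on female-labelled arrays, -0.2925 to 0.6473 without 1 replicate), Cyp17a1 (0.1703 within slide 1, 0.4607 on male-labelled arrays, -0.5413 to 0.3155 without 1 replicate), Nr5a1 (0.07158 within slide 2, 0.02674 on female-labelled arrays, -0.06269 to 0.04916 without 1 replicate), Myh3 (-0.2426 within slide 2, -0.03549 to 0.8783 without 1 replicate) and Egr2 (-0.0598 within slide 1).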

Other observations

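The genes in this part were chosen after their values were seen, and so were the tests of kidney tissue and of pan-epithelial genes; the further lists were written when the called genes were known. Of the called genes, 8 that are known from kidney tubules and ducts rose, Tfcp2l1 and 7 others. The others were Emx2 (0.78 ± 0.09), a transcription factor gene of the ureteric bud lineage, the endocytic receptor gene Lrp2 (0.76 ± 0.08), Cys1 (0.74 ± 0.09), Tinag (0.72 ± 0.09), Elf5 (0.64 ± 0.07), Cdh16 (0.60 ± 0.08), the kidney-specific cadherin gene, and Fxyd4 (0.57 ± 0.08), a regulator of the sodium pump. Serpinb5 (-0.79 ± 0.09), Fa2h (-0.77 ± 0.10) and Trim29 (-0.54 ± 0.08), which stratified epithelia express, fell, as did Perp and Sprr1a. Each of these called genes had an adjusted p under the threshold in limma and the same sign on all 4 arrays. As a group, stratified epithelium genes did not pass: of 16 further ones none was called, 9 lay below 0 and 7 above (median -0.04, camera adjusted p = 0.201), with Cdh3 at 0.69 (adjusted p = 0.0675).

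Evx1 and Hoxd13, known from posterior patterning, rose by 0.93 ± 0.14 and 0.83 ± 0.10 on the log2 scale. Over 11 other caudal Hox genes, none of them called, the median was 0.18 and 8 lay above 0 (camera adjusted p = 0.0192; adjusted p = 0.248 with an estimated correlation), with Hoxd12 at 0.60, Hoxd11 at 0.40 and Hoxa13 at 0.37, and with Hoxa10 at -0.04, Hoxa9 at -0.06 and Hoxc11 at -0.11. Other genes that rose included the forkhead gene Foxa2 (0.76 ± 0.11), Celsr1 of planar cell polarity (0.88 ± 0.13), and the BMP family ligand and antagonist genes Gdf5 (0.73 ± 0.10) and Sostdc1 (0.53 ± 0.08). The chemokine gene Ccl11 (-0.82 ± 0.09) and the adhesion molecule gene Vcam1 (-0.78 ± 0.11) fell.

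These called genes of both kinds were weighed as a pattern. Kidney tissue in the cDKO dissections stays open: the kidney and nephron progenitor list had a median of 0.0896 (SD 0.194) against 0.726 for the 8 genes, which were picked because they rose, but its median level in control ureters was no lower than theirs, so a small share could be hidden, and Pax8 (0.47), Ret (0.46) and Pax2 (0.26) lay above 0. For a larger share of epithelium, the test fixed first was open: the median of 16 further stratified epithelium genes was -0.0425, below 0 on 3 of the 4 arrays and not on all. The pan-epithelial median of 0.0961 (SD 0.183), a test added when the first had not decided, showed little rise of epithelial genes as a set. The highest of the 15 was Cldn3 at 0.51, which did not pass, and the lowest of the 8 genes was Fxyd4 at 0.57. The 8 were picked among called genes, whose smallest change was 1.392-fold. A gap to an unselected list was therefore fixed in part by that choice, and it does not decide on a larger share. A hypothesis is that the cDKO epithelium may be more duct-like and less stratified. The median of 16 further collecting duct genes was 0.145, above 0 on all 4 arrays (camera adjusted p = 0.0338, and 0.248 with an estimated correlation). None of the 16 was called, 13 lay above 0 and 3 below, namely Mal (-0.48), Aqp3 (-0.14) and Aqp2 (-0.10). The median of the stratified genes was below 0 on 3 of 4 arrays, and they did not pass (camera adjusted p = 0.201), so the hypothesis stays open.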
